A study of Homo sapiens with 4 samples.

How the data were processed

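The 4 libraries came from cells derived from H1, an established human embryonic stem cell line, carrying an mCherry reporter at UCP1, the gene of the brown adipocyte uncoupling protein. Per the labels' protocols, the reporter cells formed embryoid bodies for 7 days, mesenchymal outgrowths were passaged, and the cells then received 3 lentiviral constructs with doxycycline-inducible PPARG, CEBPB and PRDM16. They were kept in adipogenic medium with 700 ng/mL doxycycline for 14 days and matured without doxycycline for at least 6 days. Cells were detached with trypsin, digested with Liberase, stained with DAPI and sorted by mCherry fluorescence directly into lysis buffer. Libraries were made with a stranded mRNA kit and sequenced on a HiSeq4000. The groups were taken from the labels: 2 mCherry-positive and 2 mCherry-negative libraries, numbered 1 and 2 within each group. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

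The deposited table held 1 log2 expression value per gene and library for 48804 genes, each with an Ensembl identifier and a gene name. The submitters' processing notes name bcl2fastq 2.19, cutadapt, STAR 2.5.2b, HTSeq 0.6.1, DESeq2 1.6.3 and the genome build hg19, without their roles or order. The transform that made the deposited log2 values is not given in the sources used here. The values ranged from -2.26 to 20.49, and 21286 genes were listed at exactly 0 in all 4 libraries while the other 27518 were at 0 in none. That form is the one a regularized log transform gives, and this is an inference from the values. Such a transform shrinks the differences between libraries for genes with few reads. Fold changes of low genes are then understated, and so is the scatter between replicates, so that standard errors and p-values of such genes can be too small. Raw counts were not used here and the sequencing depth of each library is unknown. No counting interval or detection floor is given for that reason.

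The values were used on the log2 scale as deposited, with no pseudocount, since they were already logarithms; the design fixed before the data were examined had assumed linear values and the logarithm of the value plus 1. Genes were tested if their value reached the log2 of 10 (3.32) in at least 2 libraries, which left 15958 genes. limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the single term) gave the log2 fold change, mCherry-positive minus mCherry-negative, its standard error (SE) and a two-sided p, adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The residual degrees of freedom were 2, and limma's prior added 7.69. Fold changes are on the scale of the deposited values. Of the tested genes, 15624 matched GENCODE version 29 by Ensembl identifier and 13818 were protein coding there. That annotation is on a later build than hg19, so it was used for gene types and no coordinates are given.

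A set of 30 gene lists was fixed before the data were examined: brown and beige adipocyte, general adipocyte, metabolic pathways, cell types that the culture or the sort gate could hold, and stress programmes. A list was tested with at least 3 measured members, which left 29; the list of mitochondrially encoded genes had 0 tested members and was not analysed here. For each list the members past the threshold were counted, also adjusted over the list alone. limma's camera compared each list with all other genes at a preset inter-gene correlation of 0.01, adjusted over the lists. It was rerun with a correlation estimated from the 4 libraries. fry asked whether a list's members moved on balance one way. The genes named were UCP1, PPARG, CEBPB and PRDM16, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean level of at least the log2 of 100 and groups that did not overlap. Up to 4 members of each list with the smallest p completed the rule. A gene named outside this rule is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here. Where a symbol had several rows, the row with the highest mean was used. Paralogous genes such as SAA1 and SAA2, CKMT1A and CKMT1B or the keratins can share reads, and their separate values are uncertain. A further 4 lists (islet endocrine, acinar pancreas, keratinocyte and sebocyte genes) were written after the data had been seen and serve the closing observations only.

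The gene test and the list test were tested on simulated data with 15958 genes, of which 200 were changed for the gene test. In the data 61.1% of the tested genes passed, so the adjusted threshold was less strict there. The recoveries and false calls of the simulation need not hold for the data. With gene SDs drawn from limma's own fitted prior, 42% of genes changed by 0.5 on the log2 scale were recovered, 90% of those changed by 1 and 100% of those changed by 2 or 3, with 10 false calls. With the genes' residual SDs resampled, a harder setting and the one tried first, recovery was 4%, 48%, 88% and 96% for the same sizes, with 1 false call. A first requirement on recovery was not met in that harder setting, and the requirement was then set on the other one. A simulated list of 20 genes moved by 0.5 was called by camera, and 0 of 20 unmoved lists were. The simulated genes varied independently of each other, so that 0 does not cover false calls among lists whose members vary together.

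The alternatives set before the data were examined and run here were quantile normalization, no filter, a stricter filter (value of at least the log2 of 100), limma without trend, a test against a 1.5-fold change (treat), pseudocounts of 0.1 and 10 on the back-transformed values, the replicate number as a block, each library left out in turn, camera on ranks, camera with an estimated correlation, and fry. A pseudocount of 1 and scaling to equal totals of the back-transformed values were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.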

Results

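Gene expression was measured by RNA sequencing in human cells sorted by the fluorescence of an mCherry reporter at UCP1, after directed differentiation of H1 embryonic stem cells towards brown adipocytes. There were 2 mCherry-positive and 2 mCherry-negative libraries. The depth of the libraries is unknown, because the values are normalised log2 expression levels. Summed after back-transformation, they came to 22780000 and 22650000 in the mCherry-negative libraries and to 19200000 and 19930000 in the mCherry-positive libraries. The question, from the title and design of the series, was how the cells that switched on the UCP1 reporter differed from those that did not.

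The 2 sorted populations had distinct transcriptomes. Across the 15958 tested genes, the Pearson correlation of log2 values was 0.997 between the mCherry-negative libraries and 0.996 between the mCherry-positive libraries, and it ranged from 0.948 to 0.954 for pairs across the sort. These correlations are across genes, which are not independent replicates. The first principal component held 93.4% of the variance and separated mCherry-positive from mCherry-negative libraries. Genes of collagen I and III (COL1A1, COL1A2 and COL3A1), the main fibrillar collagens of connective tissue, together took 12.2% and 11.8% of the back-transformed total in mCherry-negative libraries and 2.36% and 2.79% in mCherry-positive libraries. Among the tested genes, 0 had equal values at the deposited precision in any pair of libraries. In mCherry-positive replicate 1, 44 of the 27518 genes with a value lay more than 1 on the log2 scale above all 3 other libraries, against 16 in mCherry-positive replicate 2 and 12 and 3 in the mCherry-negative libraries. Farthest above was INS, the insulin gene, chosen after its values were seen, at 9.49 there and 3.18 to 3.40 in the other 3 libraries.

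UCP1 (ENSG00000109424), the proton carrier of brown adipocyte mitochondria and the locus of the reporter, had the largest rise of any gene that met the naming rule. Its level was 6.17 ± 0.12 (SD, n = 2) in mCherry-negative and 10.74 ± 0.28 (SD, n = 2) in mCherry-positive cells, a difference of 4.57 ± 0.14 (SE) on the log2 scale or 23.7-fold (limma, adjusted p = 2.69e-08). Because the cells were sorted on this locus, the rise is what the gate selected and is not independent evidence of a cell state. Of the 3 delivered factors, PPARG (ENSG00000132170), the master regulator of adipogenesis, rose by 1.11 ± 0.13 (SE), or 2.16-fold (limma, adjusted p = 4.17e-05). CEBPB (ENSG00000172216), an early adipogenic transcription factor, rose by 0.90 ± 0.13 (SE), or 1.86-fold (limma, adjusted p = 0.00018). PRDM16 (ENSG00000142611), a regulator of brown adipocyte identity, went the other way: it was 2.37-fold lower in mCherry-positive cells, with a log2 difference of -1.24 ± 0.17 (SE) and limma adjusted p = 0.000114. PRDM16 read 12.42 and 11.74 in the mCherry-negative libraries and 10.86 and 10.81 in the mCherry-positive ones. Values per gene do not separate vector-borne from endogenous transcripts of these factors.

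The genes with the largest rises after UCP1 were PLA2G2A, THRSP, KRT79, GPD1, TRIM31, SAA2, ADIPOQ, FFAR4 and SAA1. PLA2G2A, a secreted phospholipase, rose 19.1-fold, and THRSP, a regulator of lipogenesis, rose 16.5-fold, with limma adjusted p of 2.61e-08 and 1.83e-07. GPD1, the enzyme that makes glycerol 3-phosphate for triglycerides, rose 11.7-fold, and FFAR4, a receptor for long-chain fatty acids, rose 10.3-fold, with limma adjusted p of 3.63e-08 and 2.61e-08. The acute-phase genes SAA2 and SAA1 rose 11.4-fold and 9.67-fold, the keratin gene KRT79 rose 14.1-fold and TRIM31 rose 11.6-fold. ADIPOQ, which encodes the adipocyte hormone adiponectin, rose by 3.46 ± 0.44 (SE) on the log2 scale, or 11.0-fold (limma, adjusted p = 8.33e-05). Its 2 mCherry-positive libraries lay far apart: without mCherry-positive replicate 1 its rise was 21.1-fold, and without mCherry-positive replicate 2 it was 5.71-fold.

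The gene with the largest fall was NPNT, a basement membrane protein, which was 15.0-fold lower in mCherry-positive cells (log2 difference -3.91 ± 0.20, SE, limma adjusted p = 1.84e-07). The smooth muscle genes MYH11, ACTG2 and LMOD1 were lower by 9.50-fold, 7.61-fold and 5.90-fold. OXTR, the oxytocin receptor, was 8.92-fold lower, THY1, a surface marker of mesenchymal stromal cells, 6.40-fold, and PCOLCE, an enhancer of procollagen processing, 6.07-fold. FOXS1, MEOX2 and TMEM119 were lower by 5.95-fold, 5.92-fold and 5.92-fold. limma's adjusted p for these 10 genes reached at most 6.8e-07.

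**Figure D1:**
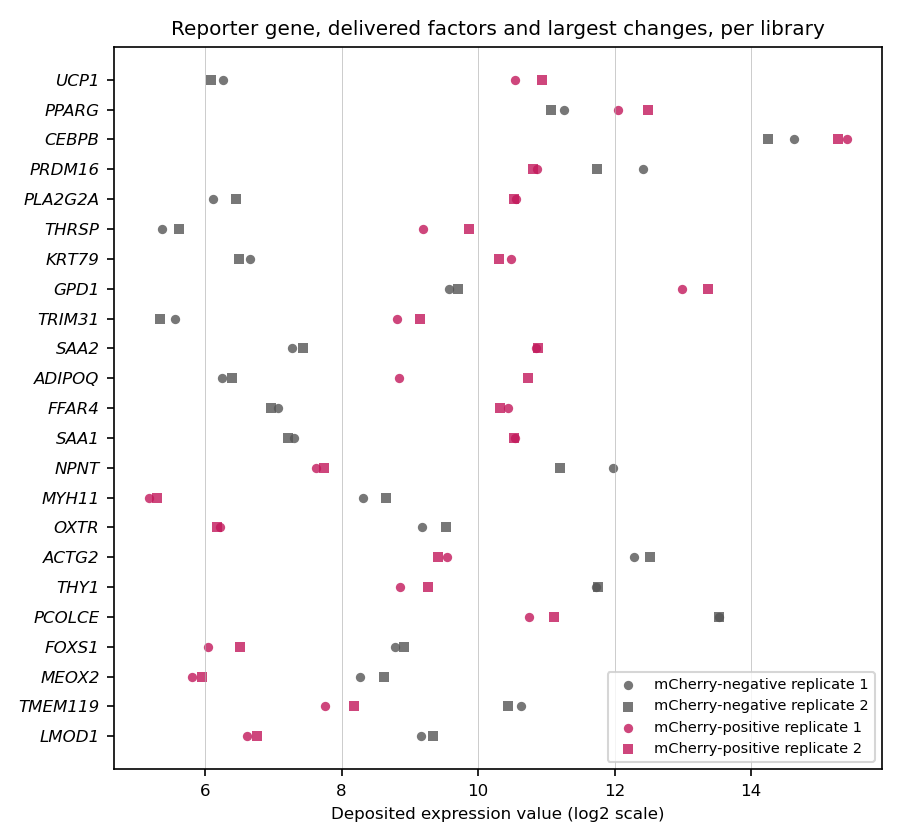
Deposited log2 expression value (horizontal axis) of UCP1, the 3 delivered factors and the genes with the largest rises and falls (vertical axis), with 1 point per library; colour gives the sorted group and shape the replicate number. UCP1 lies near 6.17 in mCherry-negative and 10.74 in mCherry-positive cells, PRDM16 is lower in both mCherry-positive libraries, and the 2 mCherry-positive values of ADIPOQ are farther apart than those of the other genes shown.

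Over all tested genes, 9752 (61.1%) passed the threshold of limma's test, 4778 higher and 4974 lower in mCherry-positive cells. Among these, 1204 rose and 1837 fell at least 2-fold, and 193 rose and 328 fell at least 4-fold. The groups did not overlap for 13129 genes (82.3%), where chance alone gives 33.3% with 2 libraries against 2. Tested against a 1.5-fold change rather than no change, 3261 genes passed, 1335 higher and 1926 lower. With each library scaled to the same back-transformed total, an alternative added after the data were seen, the median log2 fold of all tested genes moved from -0.01 to 0.21 and the split became 7146 higher and 3518 lower (67% higher, against 49%).

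Of the 29 gene lists tested, camera called 21 at its preset correlation, 11 higher and 10 lower in mCherry-positive cells. With a correlation estimated from the 4 libraries camera called 0, and 0 had an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 25: these 21 and the lists of skeletal and cardiac muscle, pluripotent stem cell, endoplasmic reticulum stress and hypoxia genes. The smallest adjusted p with an estimated correlation was 0.402. Counts adjusted over the list alone were equal to those over all genes except where given. Lists share members, such as 8 of the 13 lipolysis genes and 10 of the 27 general adipocyte genes.

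Genes of adipocytes were higher in mCherry-positive cells. Of the 27 general adipocyte genes tested, 23 rose and 3 fell (camera adjusted p = 9.01e-07, adjusted p = 0.428 with an estimated correlation). PLIN1, which coats lipid droplets, rose 9.62-fold, GPD1 11.7-fold, ACSL1, which activates long-chain fatty acids, 5.11-fold, and RBP4, a retinol carrier, 3.48-fold. CEBPA, a factor that maintains the adipocyte state, rose 3.17-fold, and FABP4, a fatty acid carrier, 1.54-fold; both were chosen after their values were seen, and FABP4 no longer passed without mCherry-positive replicate 2 (1.15-fold, limma adjusted p = 0.0859). The members that fell were CAV1 and PTRF, which build caveolae, by 2.58-fold and 2.52-fold, and PCK1, an enzyme of glyceroneogenesis, by 2.63-fold. CAV2, the other caveolin of the list, rose 2.16-fold. These genes too were chosen after their values were seen.

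The brown and beige adipocyte list went mostly, but not wholly, the same way as the general list. Of its 32 tested genes, 20 rose and 5 fell (camera adjusted p = 0.0016, adjusted p = 0.428 with an estimated correlation), and UCP1 among the 20 is the gene on which the cells were sorted. CIDEA, a lipid droplet protein typical of brown fat, rose 7.83-fold, ELOVL3, which elongates very long fatty acids, 4.77-fold, and CKMT1A, a mitochondrial creatine kinase, 4.19-fold. PPARGC1A, a coactivator of mitochondrial biogenesis, rose by 0.49 on the log2 scale and PPARA by 1.33, both chosen after their values were seen; PPARGC1A no longer passed without mCherry-positive replicate 2 (limma adjusted p = 0.0694). The 5 that fell, also chosen after their values were seen, included markers of early or classical brown fat. They were EBF2, a brown precursor factor (log2 difference -2.11), TMEM26, a beige marker (-1.57), DIO2, the deiodinase that activates thyroid hormone (-1.32), and NNAT (-0.93), with ZIC1, a marker of classical brown adipocytes, 4.00-fold lower. The mCherry-positive libraries of TMEM26 lay apart, at 3.96 and 5.23: it was 1.91-fold lower without mCherry-positive replicate 1 and 4.60-fold lower without mCherry-positive replicate 2.

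Most tested genes of triglyceride synthesis and all those of lipolysis were higher in mCherry-positive cells. Of 21 genes of fatty acid and triglyceride synthesis, 17 rose and 2 fell (camera adjusted p = 2.7e-06, adjusted p = 0.41 with an estimated correlation). GPAM and DGAT2, acyltransferases of the first and last steps of triglyceride assembly, rose 7.75-fold and 5.97-fold. MGST1, a glutathione transferase that is no enzyme of that assembly, rose 3.80-fold. The 2 that fell were the desaturases SCD5 (3.21-fold) and FADS2 (1.84-fold), and DGAT1 and SREBF1 did not pass (limma adjusted p = 0.275 and 0.522); these 4 were chosen after their values were seen. All 13 tested lipolysis genes rose (camera adjusted p = 1.7e-06, adjusted p = 0.402 with an estimated correlation). Among them, PDE3B, which breaks down cyclic AMP, rose 6.47-fold, PRKAR2B, a regulatory subunit of protein kinase A, 4.13-fold, and ABHD5, the coactivator of adipose triglyceride lipase, 2.54-fold. The list was not split into members that drive and members that restrain lipolysis, so the count gives no direction for the process.

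Genes of lipid and energy metabolism in mitochondria and peroxisomes were also higher, with smaller folds. In the citric acid cycle list 17 of 22 genes rose and 1 fell (camera adjusted p = 1.43e-05, adjusted p = 0.402 with an estimated correlation), led by PDHA1 and DLAT, subunits of pyruvate dehydrogenase, 2.54-fold and 2.42-fold, and IDH2 at 2.21-fold. In the fatty acid oxidation list 15 of 26 rose and 4 fell, with 16 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00162, adjusted p = 0.578 with an estimated correlation). SLC25A20, the carnitine carrier, rose 2.32-fold and ACOT2, a mitochondrial acyl-CoA thioesterase, 2.52-fold, whereas CPT1A, the liver-type carnitine transferase, was 1.37-fold lower and EHHADH, ETFB and ACADM were 1.48-fold, 1.26-fold and 1.25-fold lower; the 4 that fell were chosen after their values were seen. Of these, EHHADH, ETFB and ACADM did not pass without mCherry-negative replicate 1 (limma adjusted p = 0.161, 0.0623 and 0.117), nor ETFB and ACADM without mCherry-positive replicate 1 (0.239 and 0.0992). Among the members that rose, ACAA2, chosen after its value was seen, went from 0.27 to 0.16 on the log2 scale without mCherry-negative replicate 2. With equal totals 19 members were higher and 1 lower, and with quantile normalization 14 were higher and 3 lower. In the peroxisome list 15 of 22 rose and 1 fell (camera adjusted p = 3.78e-05, adjusted p = 0.402 with an estimated correlation), with PEX11A, which drives peroxisome division, at 4.17-fold. The member that fell was EHHADH, whose fall was not called without mCherry-negative replicate 1, and 0 members were lower with quantile normalization (16 higher) or equal totals (18 higher).

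Of 76 nuclear-encoded respiratory chain and ATP synthase genes, 40 rose, 1 fell and 35 did not pass, with 38 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.4e-06, adjusted p = 0.402 with an estimated correlation). The largest member changes were small: SDHD rose 1.89-fold, COX7B 1.80-fold and NDUFS1 1.78-fold, and the median over members was 0.23 on the log2 scale. The median was 0.44 and 68 members were higher and 0 lower when libraries were scaled to equal totals, which moved all genes up by a similar amount. ATP5G2, the member that fell (1.20-fold), was chosen after its value was seen, as was UQCRC2. The rise of UQCRC2 went from 0.19 on the log2 scale to 0.11 without mCherry-negative replicate 2, where it no longer passed. Other members that rose, such as NDUFB4 and SDHA, chosen after their values were seen, also lost their call when 1 library was left out. NDUFB4 went from 0.19 to 0.13 without mCherry-negative replicate 2.

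Cholesterol synthesis genes rose, 19 of 23 with 1 lower, or 20 with 1 lower adjusted over the list alone (camera adjusted p = 4.36e-07, adjusted p = 0.402 with an estimated correlation). SC5D rose 3.52-fold and MSMO1 2.90-fold, both enzymes of the late sterol pathway. PMVK, a kinase of the mevalonate pathway, was 1.30-fold lower and was chosen after its value was seen; with equal totals 21 members were higher and 0 lower. Glycolysis genes moved both ways, 11 higher and 7 lower of 21 (camera adjusted p = 0.555), with HK2, a hexokinase, 2.24-fold higher and PFKM, the muscle phosphofructokinase, 2.61-fold lower; the list's median was 0.21 and its mean -0.02.

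Genes of connective tissue were lower in mCherry-positive cells. All 31 tested genes of the fibroblast extracellular matrix fell (camera adjusted p = 2.37e-15, adjusted p = 0.402 with an estimated correlation), with a median log2 difference of -2.18. THBS2, a matrix glycoprotein, was 5.61-fold lower, TNC 4.97-fold, LOXL1, a collagen and elastin cross-linking enzyme, 4.54-fold and TIMP1 3.72-fold. Of 18 smooth muscle and myofibroblast genes, 15 fell and 0 rose, or 17 and 1 adjusted over the list alone (camera adjusted p = 5.58e-08, adjusted p = 0.402 with an estimated correlation), and 1 rose with quantile normalization or equal totals. ACTA2, smooth muscle actin, was 5.65-fold lower, and TPM2 and TGFB1I1 were 5.31-fold and 5.23-fold lower.

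Mesenchymal progenitor and preadipocyte genes fell in 21 of 27 cases and rose in 5 (camera adjusted p = 2.93e-05, adjusted p = 0.428 with an estimated correlation). PRRX1, a mesenchymal transcription factor, was 4.77-fold lower and PDGFRB, the platelet-derived growth factor receptor beta, 4.64-fold. DPP4, a surface protein of adipose progenitors, went against the list and rose 2.94-fold. MCAM (2.34-fold), CD55 (1.66-fold), CD44 (1.63-fold) and GATA3 (1.57-fold) also rose and were chosen after their values were seen. Cartilage and bone genes fell in 8 of 9 cases (camera adjusted p = 0.000502, adjusted p = 0.402 with an estimated correlation), including COL2A1, 6.12-fold lower, and RUNX2, the osteoblast regulator, 4.20-fold lower.

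**Figure D2:**
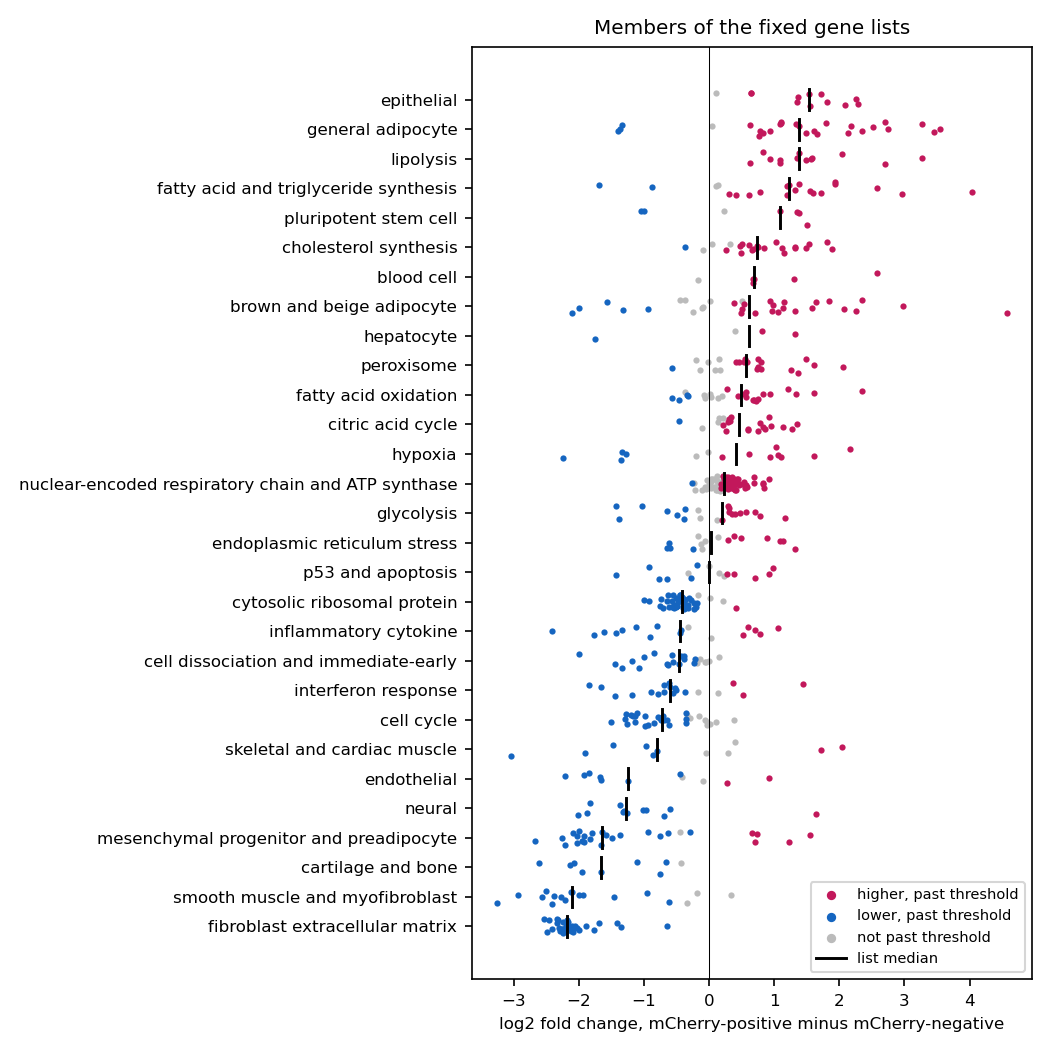
Log2 fold change, mCherry-positive minus mCherry-negative (horizontal axis), of each tested member of the 29 fixed gene lists (vertical axis); each point is 1 gene, coloured by whether it passed the threshold higher or lower, and the black bar is the list median. The medians run from -2.18 for the fibroblast extracellular matrix, where all 31 genes fell, to 1.54 for epithelial genes, where 11 of 12 rose.

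Markers of other cell types moved with the sort, beside the adipocyte and matrix lists. Epithelial genes were higher in mCherry-positive cells, 11 of 12 with 0 lower (camera adjusted p = 9.01e-07, adjusted p = 0.402 with an estimated correlation): CDH1, epithelial cadherin, rose 4.86-fold, CLDN7 4.26-fold, KRT19 3.49-fold and KRT8 2.93-fold. Of the 16 listed blood cell genes only 6 were tested, and 5 of these rose (camera adjusted p = 0.0315, adjusted p = 0.402 with an estimated correlation). CSF1R, a macrophage receptor, rose 6.00-fold and CD14 2.47-fold, while LYZ and ITGAM each rose by 0.67 on the log2 scale, from levels below the log2 of 10. HBA1, chosen after its value was seen, rose by 0.69. It rose by 0.56 without mCherry-negative replicate 2 and by 0.48 without mCherry-positive replicate 2, and it passed in neither fit. The blood cell call was lost without the filter on low values (camera adjusted p = 0.0511) and with equal totals (camera adjusted p = 0.0713), and LYZ without mCherry-negative replicate 2 (adjusted p = 0.0924) and ITGAM without mCherry-negative replicate 1 (adjusted p = 0.0764) no longer passed limma's test.

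Neural genes fell in 11 of 12 cases (camera adjusted p = 0.00152, adjusted p = 0.402 with an estimated correlation), with GAP43 4.04-fold and SYT1 3.54-fold lower, and PAX6, chosen after its value was seen, rose 3.11-fold. Endothelial genes fell in 7 of 11 cases and rose in 2 (camera adjusted p = 0.0315, adjusted p = 0.402 with an estimated correlation), with CDH5, vascular cadherin, 4.63-fold lower; this call was lost with the stricter filter (camera adjusted p = 0.177). Skeletal and cardiac muscle genes went both ways, 2 higher and 6 lower of 11 (camera adjusted p = 0.367, fry adjusted p = 0.0347), with TNNT2 8.26-fold lower and MYL3 4.13-fold higher. Hepatocyte genes (2 higher and 1 lower of 4, camera adjusted p = 0.462) and pluripotency genes (4 higher and 2 lower of 7, camera adjusted p = 0.15) were not called by camera, while fry called the pluripotency genes (adjusted p = 0.0124). Among single members, SERPINA1 was 2.49-fold higher, FGG 3.35-fold lower, and the stem cell genes L1TD1 and LIN28B 2.83-fold and 2.59-fold higher. TF was 1.76-fold higher with limma adjusted p = 0.0126, which became 0.111 without mCherry-negative replicate 2 and 0.0568 without mCherry-positive replicate 2.

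Growth and stress programmes also differed. Cell cycle genes fell in 23 of 32 cases and rose in 0, or 23 and 1 adjusted over the list alone (camera adjusted p = 2.93e-05, adjusted p = 0.428 with an estimated correlation), with UBE2C 2.84-fold and CENPF 2.44-fold lower; with equal totals 19 were lower and 2 higher. Cytosolic ribosomal protein genes fell in 43 of 48 cases and rose in 1 (camera adjusted p = 5.58e-08, adjusted p = 0.402 with an estimated correlation), with RPS4X 2.01-fold and RPL10 1.89-fold lower; with equal totals 26 were lower and 3 higher, and their median went from -0.42 to -0.20. RPS27, the member that rose, was 1.34-fold higher and was chosen after its value was seen. It did not pass when any 1 of the 4 libraries was left out (1.31-fold to 1.36-fold). Some members that fell were no firmer, such as RPS13 and RPS25, chosen after their values were seen. RPS13 went from -0.23 to -0.09 on the log2 scale without mCherry-negative replicate 2. RPS25 went from -0.19 to -0.13 without mCherry-positive replicate 2. Immediate-early and dissociation genes fell in 17 of 23 cases and rose in 0 (camera adjusted p = 0.000345, adjusted p = 0.402 with an estimated correlation), with NR4A1 3.98-fold and FOSB 2.26-fold lower; with equal totals 12 were lower and 1 higher, and their median went from -0.46 to -0.24. FOS and JUN, chosen after their values were seen, differed by -0.18 and -0.06 and did not pass (limma adjusted p = 0.174 and 0.572).

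Interferon response genes fell in 14 of 19 cases and rose in 3 (camera adjusted p = 0.00132, adjusted p = 0.402 with an estimated correlation). IFITM1 was 3.58-fold and MX2 3.15-fold lower, whereas OASL was 2.71-fold higher. Inflammatory cytokine genes went both ways, 5 higher and 10 lower of 17 (camera adjusted p = 0.178), with the chemokine gene CCL2 5.32-fold lower and IL1A 2.09-fold higher; without mCherry-negative replicate 1 the list was called lower (camera adjusted p = 0.0284). The lists of endoplasmic reticulum stress (7 higher and 4 lower of 16, camera adjusted p = 0.402), hypoxia (8 higher and 4 lower of 14, with 5 lower adjusted over the list alone, camera adjusted p = 0.269) and p53 and apoptosis (5 higher and 6 lower of 15, with 6 higher adjusted over the list alone, camera adjusted p = 0.931) were not called by camera, while fry called endoplasmic reticulum stress (adjusted p = 0.0159) and hypoxia (adjusted p = 0.0171). With equal totals the split of the p53 list turned, to 8 higher and 4 lower with a median of 0.22, a shift close to the 0.21 of all genes. Members of these lists, DDIT4 (2.49-fold) and BNIP3 (3.05-fold), were higher, and LOX (4.71-fold) and PMAIP1 (2.68-fold) were lower. As deposited, the p53 list had a median of 0.00 and a mean of -0.06 with camera's direction upwards.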

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

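The pseudocount of 1 and the scaling to equal totals were chosen after the data had been seen, and the other alternatives were set before. Raw counts were not used here, so edgeR with either scaling, DESeq2, voom and thinning were not run. The number of genes past the threshold stayed within 1.5 times the 9752 found under every alternative run except the test against a 1.5-fold change, a stricter question by construction, which gave 3261 (1335 higher and 1926 lower). Leaving out 1 library gave 8503 to 8817 genes, the lone library being assumed to vary like the other group. The split changed with equal totals (7146 higher and 3518 lower) and less with quantile normalization (5246 and 4606). UCP1 stayed past the threshold under all alternatives run, at 4.37 to 4.78 on the log2 scale.

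Camera called 19 to 22 lists under the alternatives other than the estimated correlation, where it called 0 and fry 25; with 4 libraries such a correlation rests on 2 residual degrees of freedom. The p53 and apoptosis list, never called, changed direction with quantile normalization (adjusted p = 0.988), the replicate block (0.877) and without mCherry-negative replicate 1 (0.809, leave-one-out fits reaching 0.995); the cause was not tested. The lowest correlation within a group exceeded the highest across groups by 0.0422, by 0.00811 without the filter and by 0.0973 with the stricter one, which differ in the genes included. Of the 131 named genes, 7 lost their call against 1.5-fold, among them CEBPB, CDKN1A, RPL3, ITGAM, LYZ and TF, and APOB (adjusted p = 0.0795) gained one with quantile normalization (0.0413), no trend (0.0244) and equal totals (0.0109).

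The replicate numbers are shared by both groups, and the labels do not say whether same-numbered libraries are paired. The replicate differences of the groups correlated at r = 0.0754 across genes. No strong shared shift was seen, which does not settle whether the libraries were paired. With the number as a block, 10194 genes passed (4980 higher and 5214 lower) and 22 lists were called, the added one being inflammatory cytokines (camera adjusted p = 0.0303). Depth is unknown, so how far it limits low genes could not be computed.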

Other observations

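The lists used here were written after the data had been seen, from genes not among those that drew attention, and the tests on the pancreas lists, on SFN and SERPINB5 against KRT16 and on the replicates of mCherry-positive cells were chosen only after their results or member values had been seen.

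Some genes known from the epidermis were among those higher in mCherry-positive cells. KRT16, a keratin of activated epidermis, rose by 3.24 ± 0.07 (SE, n = 2 per group) on the log2 scale, TGM3, an epidermal transglutaminase, by 3.11 ± 0.07, KRT6A by 3.08 ± 0.10 and SERPINB3 by 2.84 ± 0.10. CAMP, the gene of an antimicrobial peptide, rose by 3.05 ± 0.07, and FAR2, which makes fatty alcohols for waxes, by 2.70 ± 0.07. Other genes that rose were TNMD by 3.10 ± 0.10, MRAP, an accessory protein of the ACTH receptor, by 3.18 ± 0.19, KLB, the co-receptor of FGF21, by 3.10 ± 0.16, and TSHR by 2.81 ± 0.14. Each passed limma's test with both mCherry-positive libraries above both mCherry-negative ones, and each was chosen after its values were seen.

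The epidermal genes were weighed against keratinocytes in the mCherry-positive sort and against a sebocyte-like programme. Of 32 tested keratinocyte genes (0 of the list in the fixed lists), 22 rose and 5 fell, with a median of 1.14 (camera adjusted p = 0.000141, adjusted p = 0.191 with an estimated correlation), and KRT5 and KRT14 both rose, by 1.87 and 1.98, as keratinocytes would require, although keratins can share reads. Against keratinocytes as the source of most KRT16 mRNA stood SFN and SERPINB5, abundant in them and no keratins. Their levels differed from that of KRT16 by -7.58 and -11.3 in mCherry-positive libraries, and TP63 fell by 1.88 between the groups. However, PERP and DSP, also abundant in keratinocytes, read 11.65 and 11.79 in mCherry-positive libraries. S100A8, S100A9 and LCN2, listed with them, read 13.61, 14.99 and 14.99 there and rose by 1.56, 1.38 and 2.08, so the members that are no keratins point both ways. Of 22 sebocyte genes (3 of the list in the fixed lists), 12 rose and 3 fell, with a median of 0.422 (camera adjusted p = 0.0297, adjusted p = 0.296 with an estimated correlation), short of the 0.5 set in advance, which leaves a sebocyte-like programme in reporter-positive cells open. A small share of keratinocytes may remain. The mCherry gate selects against cells that do not fluoresce, but the purity of the sort is unknown.

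In mCherry-positive replicate 1 INS, the insulin gene, read 9.49 against 3.18 to 3.40 in the other 3 libraries, 79.6-fold over mCherry-positive replicate 2 and 0.00375% of the library's back-transformed total; insulin in the medium is a protein and brings no mRNA. Reads of the neighbouring IGF2 are argued against, as IGF2 differed by -0.412 between replicates 1 and 2, and so is whole pancreas, where acinar mRNAs exceed that of insulin. The median level of 13 acinar genes differed from that of INS by -8.55 in replicate 1. Of these, 0 lay over 1 above every other library, although their median difference was 0.263 (percentile 99.98). CPA1, an acinar gene left out because it had drawn attention, read 5.04 in replicate 1 and 3.77 in replicate 2. In the mCherry-negative libraries CPA1 read 5.44 and 5.52. Over the 14 islet endocrine genes that passed the filter (5 of the list are in fixed lists), the version run first, the median difference, replicate 1 minus 2, was 0.102 (percentile 99.33 of 10000 random lists matched on expression), and the list was not called between the sorted groups (4 higher and 6 lower, camera adjusted p = 0.457). The percentiles rest on 1 library against 1 and on random genes drawn independently. Lists whose members vary together reach high percentiles more easily, such as the fixed hypoxia list at 98.64 in the same direction. Over all genes with a value, a set widened after member values had been seen, the median was 0.508 for 34 endocrine genes (percentile 100), with GCG at 8.19, PCSK2 at 7.10, IAPP at 6.68 and SST at 4.64 and 11 genes over 1 above every other library, so that set describes the pattern more than it tests it. RNA of islets, reads of another library on the sequencer, or rare endocrine cells in this culture may each be the source. No test here separates them. The mCherry gate selects against endocrine cells that do not fluoresce, but the purity of the sort is unknown.

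Adipocyte genes were higher in mCherry-positive replicate 2 than in replicate 1, by a median of 0.388 over 27 genes (26 above 0, percentile 100 of matched random lists). If fewer mCherry-negative cells in the sort of replicate 2 were the cause, matrix genes would be lower there, but their median difference was 0.304 higher, above 0 in 96.8% of 31 genes. An unequal scale of the 2 libraries is argued against by a median of 0.0278 over all tested genes. Genes of mesenchymal progenitors (median 0.276), smooth muscle (0.256) and cartilage and bone (0.311) were also higher in replicate 2. So were immediate-early and dissociation genes (median 0.159, 17 of 23 above 0). Those genes were higher in mCherry-negative replicate 2 than in mCherry-negative replicate 1 as well (median 0.19). Between these mCherry-negative libraries, smooth muscle (0.163), mesenchymal progenitor (0.0859) and matrix genes (0.0759) went the same way. General adipocyte (-0.12) and cartilage and bone genes (-0.115) went the other way. The percentile of the adipocyte list rests on 1 library against 1 and on random genes drawn independently. Lists whose members vary together reach high percentiles more easily, such as inflammatory cytokines at 98.1. No biological explanation was tested, since the labels give no difference between the replicates.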
